A study of Mus musculus with 6 samples.

How the data were processed

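RNA-seq was run on total RNA of cultured mouse skeletal muscle satellite cells, the stem cells that rebuild muscle fibres, after 2 days in differentiation. The series holds 6 libraries, 3 from wild-type (WT) and 3 from lncMREF knockout (KO) mice, and the genotype in the labels set each library's group. Per the labels' protocols, RNA was extracted with TRIzol and the libraries were sequenced on an Illumina instrument. Per the submitters' processing notes, HISAT2 2.2.1, featureCounts 2.0.1 and the mm10 build were used. The order of these steps, the annotation release, the counting options and the use of strand are not given in the sources used here.

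The authors deposited raw counts per Ensembl gene in 2 forms: a matrix of the whole series with 21666 genes, and a table per library with 55359 genes. The values of both are whole numbers, not normalised. Matrix totals were 23844610, 20193337 and 28430678 counts in WT replicates 1 to 3 and 20861627, 23646805 and 17919826 in KO replicates 1 to 3, whereas the per-library tables summed to between 5501088 and 9136354. The 2 forms differed gene by gene. Among 9940 genes with a mean of at least 200 counts in the matrix, 5.8% had a per-library mean within 0.8 to 1.25 times the matrix mean, and the log2 means correlated across genes at 0.103 (Pearson; genes are not independent replicates). All 14 genes compared on chromosome M and all 4 on chromosome Y lay within that range. In stretches of 10 Mb with at least 20 genes compared, so did all genes on chromosome 4 between 10 and 20 Mb (21 genes), 40 and 50 Mb (84) and 50 and 60 Mb (28) and on chromosome 6 between 20 and 30 Mb (21), and 71.9% of 32 genes on chromosome 15 between 30 and 40 Mb. Some stretches with fewer genes also matched and are not described here. Actb had a mean of 25044 counts in the matrix and 34 in the per-library tables, Eef1a1 174767 against 0, Col1a1 159085 against 0 and Myh3 75025 against 0. Actb, Eef1a1 and Col1a1 were named after their values were seen. In the per-library tables, 35 gene identifiers carried the same version number as in GENCODE M21. The correlation of 0.103 is that of all 9940 genes. It was 0.094 without chromosomes M and Y, and it was not computed without the other matching stretches. Outside the matching stretches, these low correlations and such low counts argue against the per-library counts, as a set, belonging to the genes they are labelled with. For any single gene there this is open. The plan fixed before the data were examined named the per-library tables as the main source and the matrix as the alternative. The matrix was made the main source after this comparison and before any test between genotypes, and the per-library tables became an alternative. The rule by which genes were left out of the matrix is not given in the sources used here; its lowest sum over the 6 libraries was 4 counts.

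Of the matrix genes, 21632 were matched by Ensembl identifier to GENCODE M21, an annotation of the same build, and 34 were not; 15743 were protein coding. Symbols and 1-based mm10 coordinates come from that annotation. Exonic bases shared between genes on either strand were found with bedtools 2.31.1, because counting without strand would not separate overlapping or antisense genes. Genes of near-identical families, such as the myosin heavy chains, the muscle actins and the mitochondrial genes with nuclear copies, can also share reads. The targeted lncRNA could not be matched to a gene identifier, since its identifier and position are not given in the sources used here, so it is not reported and the knockout was not checked from the counts.

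Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total count 15), which left 15518 genes. Library sizes were scaled by TMM, dispersions were estimated robustly, and KO was compared with WT by edgeR's quasi-likelihood F-test with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Levels are CPM, counts divided by the TMM-scaled library size and brought to a common total, as mean ± SD over 3 libraries. Fold changes are log2 of KO over WT, and their standard errors (SE) are the fold change divided by the square root of the F statistic. The labels do not say whether the replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Replicate libraries were compared by a chi-square statistic over genes with at least 30 counts in a pair; its mean per gene ran from 3.18 to 5.11 over the 6 within-group pairs, above the 1 that sampling noise alone gives, so no pair was taken for 1 library deposited again. Repeat library preparations of a single RNA can also differ by this much, and the biological coefficient of variation was 4.9%.

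The gene lists were fixed before the data were examined: 36 lists of muscle differentiation, proliferation, signalling, metabolism, chromatin factors and markers of other cell types. Each was tested with camera (limma 3.58.1) on the edgeR fit with an inter-gene correlation preset at 0.01, two-sided, with adjustment over the lists that had at least 5 tested members. The tests were repeated with an estimated correlation and with fry. All 36 lists were called by fry, which asks whether a list's genes move on balance in one direction and does not compare them with other genes. The genes named were also chosen by a rule set beforehand. It took 12 fixed genes, and the 6 largest rises and 6 largest falls among named genes with at least 5 CPM in the higher group, an adjusted p under 0.05 and no overlap between the groups. It further took up to 4 members with the smallest adjusted p of each list called by camera, and up to 2 of the most abundant called members of each other list. The rule gave 138 genes, of which the text names a part; any other gene is named after its values were seen, and is marked so.

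The edgeR step was tested on simulated counts of 15518 genes drawn from the real means, library totals and dispersions, of which 15292 passed the filter. For KO against WT, it recovered 28 of 50 genes changed 1.25-fold, 37 of 50 at 1.5-fold, 46 of 50 at 2-fold and 49 of 50 at 4-fold. Of 177 calls, 17 (9.6%) were unchanged genes. In a second simulation, camera called the 1 list that had been moved and 0 of 35 others. Genes were drawn independently of each other there, so it cannot test the preset correlation. In the data the estimated correlation reached 0.602, for ribosomal proteins.

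Alternatives were other library factors (median of ratios, upper quartile, library size only), other filters (none, or a mean of at least 1 CPM), DESeq2 1.42.0, limma voom, a test against a fold of 1.5 (glmTreat), the replicate number as a block, and each library left out in turn. Added after the data were seen were the per-library tables, offsets per library for GC content and exon length (loess span 0.3), and thinning of every library to the total of the smallest.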

Results

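The data are gene counts of 6 RNA-seq libraries of satellite cells that had been differentiated for 2 days, 3 from WT and 3 from lncMREF KO mice. lncMREF is a long noncoding RNA, and the series title links it to muscle differentiation and to a complex of the chromatin remodeller Smarca5 and the acetyltransferase p300. The design asks which genes differ between genotypes at this time. Library totals ran from 17919826 to 28430678 counts, and the 10 most abundant genes held 7.24% to 7.93% of them. Log2 levels correlated across genes at 0.993 to 0.994 between libraries of one genotype and at 0.945 to 0.948 between genotypes. These correlations are across genes, which are not independent replicates. The first principal component held 84.7% of the variance and separated the genotypes, and the second held 4.3%. Genes encoded in mitochondrial DNA took 3.97% to 4.18% of counts in WT libraries and 2.07% to 2.3% in KO libraries.

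Most muscle differentiation genes were lower, and cell cycle genes were higher, in KO than in WT cells. Over 7 fixed lists of muscle regulators, fusion, contraction, calcium handling, membrane, junction and energy genes, 141 of 155 tested genes were lower in KO, 116 of them by over 2-fold, 7 were higher and 7 were not called. All 40 tested cell cycle genes were higher, with a median log2 fold change of 2.00. Interferon response and endothelial genes were lower, and macrophage and Schwann cell markers were higher. Of 15518 genes tested, edgeR's quasi-likelihood test called 10353 at an adjusted p under 0.05, 5123 lower and 5230 higher in KO, and 1456 and 1329 of these changed by over 2-fold. The split depends on the scaling: with library size only, the median of all genes moved from 0.021 to 0.192 and 66.1% of calls were higher in place of 50.5%. The per-library count tables, which differ from the matrix gene by gene, gave 5436 calls among 9871 genes and called 2 of 26 lists. Of the 55 measured genes of the naming rule, 17 were opposite in sign there. All 17 had mean counts outside the range taken as matching, but so did 50 of the 55, so this does not explain the 17. Outside that range the counts argue against the values, as a set, belonging to the genes named.

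Among the genes fixed by name, the myogenic transcription factors Myod1 and Myog fell. Myod1 (ENSMUSG00000009471, chromosome 7, 46376474 to 46379099) went from 302 ± 9.93 counts scaled to library size (CPM) in WT to 93.5 ± 3.73 in KO (SD, n = 3 each), a log2 fold change of -1.69 (SE 0.05, adjusted p 3.87e-27). Myog (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548) went from 749.8 ± 33.2 to 312 ± 11.8, a change of -1.26 (SE 0.04, adjusted p 7.39e-24). Myf5, which acts early in the lineage, stood at 6.53 ± 1.15 and 5.87 ± 0.109 and was not called (-0.15, SE 0.14, adjusted p 0.346). Pax7, the marker of uncommitted satellite cells, rose from 10.5 ± 0.782 to 15.1 ± 0.751 (0.53, SE 0.10, adjusted p 1.12e-05). The fusion proteins Mymk and Mymx fell by 2.19 and 1.37 on the log2 scale (SE 0.04 and 0.07). Embryonic myosin heavy chain Myh3 went from 5695 ± 238 to 948 ± 65.0, a 6.01-fold fall, skeletal actin Acta1 fell 3.7-fold and muscle creatine kinase Ckm 4.76-fold. Ckm shares 15.5% of its exonic bases with another annotated gene, and the myosin and actin genes can share reads within their families. The proliferation marker Mki67 rose from 19.1 ± 1.27 to 94.6 ± 10, a 4.98-fold rise.

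**Figure D1:**
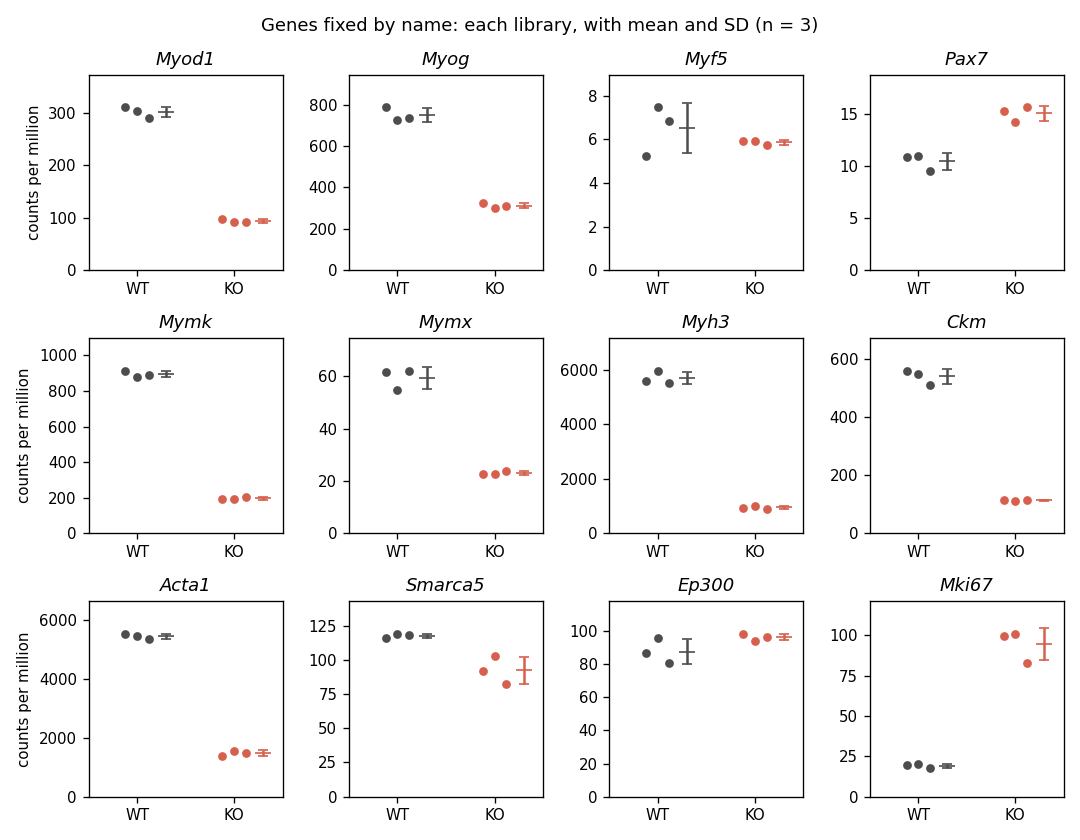
Level of the 12 genes fixed by name in each library, in CPM of the scaled library size on a linear axis from 0; points are the 3 libraries of each genotype, and the bar beside them is the mean with its SD. The libraries of both genotypes do not overlap for Myod1, Myog, Pax7, Mymk, Mymx, Myh3, Ckm, Acta1, Smarca5 and Mki67, which chance alone gives for 10% of genes, whereas those of Myf5 and Ep300 overlap.

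Of the 6 largest falls by the fixed rule, the first was that of a contractile gene. Fast myosin heavy chain Myh4 fell from 169.9 ± 4.2 to 4.56 ± 0.684 CPM, a log2 fold change of -5.21 (SE 0.07). Fam167a (-4.42), the fast myosin-binding protein Mybpc2 (-4.32), the nuclear receptor Esrrb (-4.26), the muscle gene Ky (-4.13) and the gap junction gene Gja5 (-4.02) followed, with adjusted p-values between 2.26e-30 and 2.42e-19. The largest rises were those of Thbs4, a matrix protein of tendon and muscle, from 10.5 ± 0.836 to 208.8 ± 6.56 (4.31, SE 0.06), Ptn, a heparin-binding growth factor (3.88), Col14a1, a fibril-associated collagen (3.56), the myeloid genes Trem2 (3.67) and Tyrobp (3.50), and the myelin gene Mbp (3.47). Trem2 and Tyrobp stayed low in KO, at 5.05 ± 0.798 and 5.51 ± 0.438 CPM.

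The lists of muscle differentiation fell together. Of 54 tested sarcomere and contractile genes, 52 were lower and 1 was higher (median -1.84, camera adjusted p 1.3e-82), including Actn2 at the Z-disc (-2.84), the sarcomere assembly protein Klhl41 (-2.71) and neonatal myosin heavy chain Myh8 (-2.38). The member that rose was the tropomyosin Tpm3 (0.29, SE 0.04), named after its value was seen. Of 23 calcium handling and excitation genes, 22 were lower (median -1.88, adjusted p 3.22e-49), with the calcium pump Atp2a1 at -3.05, the calcium store protein Casq1 at -2.81 and Srl at -2.39; Atp2a1 shares 21.9% of its exonic bases with a neighbour. Of 14 neuromuscular junction genes, 13 were lower (median -2.17, adjusted p 2.06e-26), among them the acetylcholine receptor subunits Chrnd (-2.62), Chrna1 (-2.53) and Chrng (-2.44). All 20 muscle energy genes were lower (median -1.57, adjusted p 4.07e-29), as for glycogen phosphorylase Pygm (-2.66) and phosphofructokinase Pfkm (-2.33). Of 15 myogenic regulators, 12 were lower (median -1.26, adjusted p 1.91e-11), with Mef2a at -1.77, Tead4 at -1.72 and Mef2c at -1.71. In the fusion list 11 of 15 were lower and 2 were higher (median -0.93, adjusted p 3.39e-12), with Jam2 at -2.27 and Tmem182 at -2.13. In the dystrophin complex list 12 of 15 were lower (median -0.96, adjusted p 4.09e-10), with the sarcoglycan Sgca at -1.87 and caveolin Cav3 at -1.64. The members that rose in the other 5 of these lists with any were Rtl1 (2.14), Agrn (0.14), Tcf12 (0.17), Sgce (0.46), Dock1 (0.54) and Kirrel (0.43), also named after their values were seen. These 7 calls held with an estimated correlation, at adjusted p-values from 0.0028 to 0.0261. The same libraries differed in mitochondrial share, in endothelial, macrophage and Schwann cell markers and in sex-linked transcripts.

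**Figure D2:**
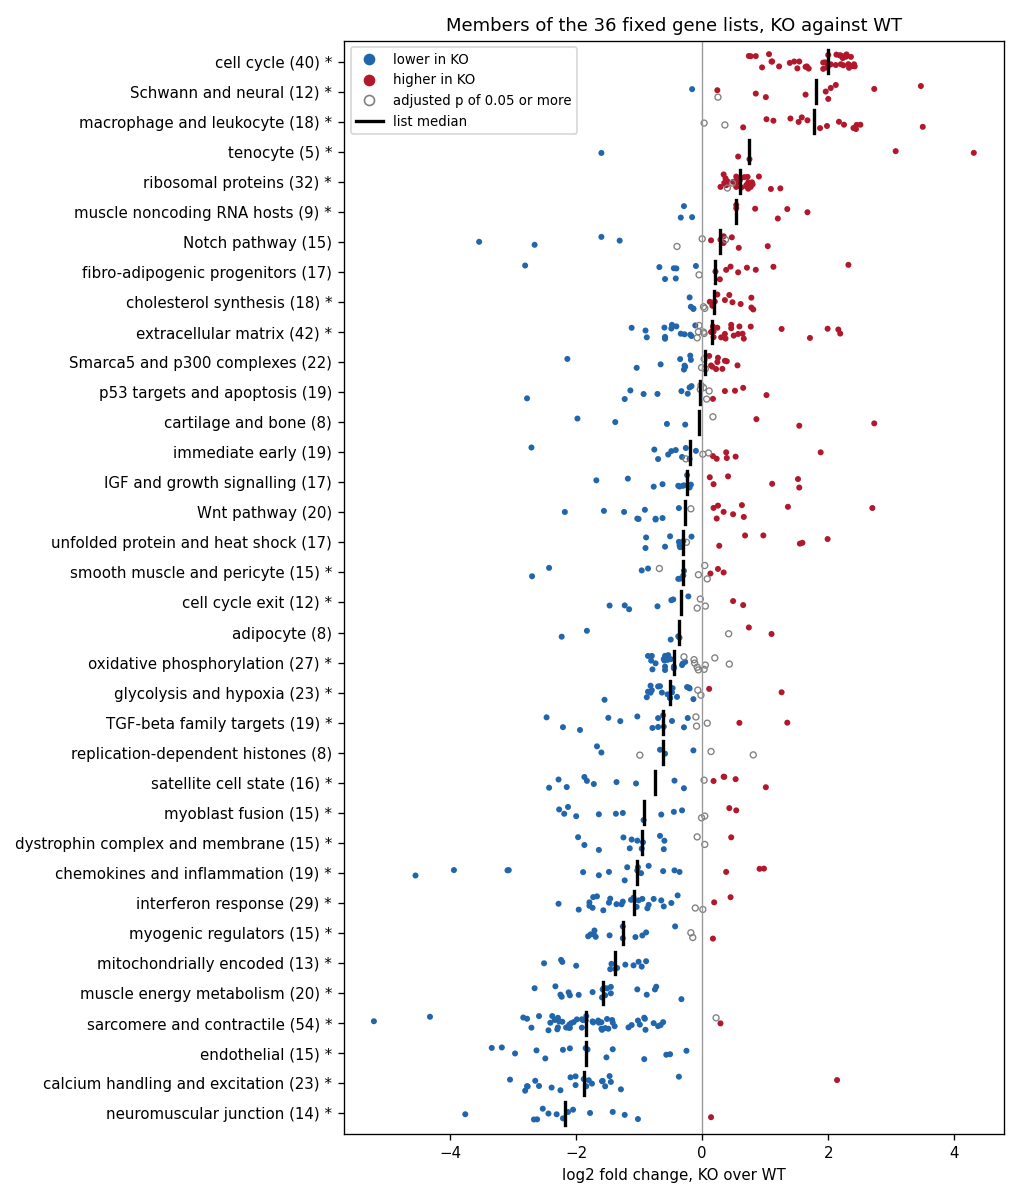
Log2 fold change of KO over WT for each tested member of the 36 fixed lists, with the number of members in brackets and an asterisk where camera with the preset correlation called the list; blue and red points were called lower and higher, open points were not called, and black bars are list medians. The medians run from -2.17 for neuromuscular junction genes to 2.00 for cell cycle genes.

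The satellite cell state list split. Of its 16 tested genes, 10 were lower and 5 were higher (median -0.75, camera adjusted p 3.71e-07; 0.0206 with an estimated correlation). The members with the smallest p were Des (-2.43), Itga7 (-1.87), Megf10 (-1.83) and Ncam1 (-1.72); Des, the muscle intermediate filament, and Ncam1 are also made by differentiating myocytes. The others that fell were Pax3 (-2.28, from 3.88 to 0.763 CPM), Cd34 (-2.15), Cxcr4 (-1.36), Sdc4 (-1.05), Spry1 (-0.44) and Itgb1 (-0.29), all named after their values were seen. The 5 that rose were Pax7 (0.53), Msc (1.01), Met (0.35), Heyl (0.34) and Fgfr4 (0.18), the last 4 named after their values were seen.

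Cell cycle genes rose without exception among the 40 tested (median 2.00, adjusted p 1.33e-42; 0.0133 with an estimated correlation). Topoisomerase Top2a went from 28.6 ± 0.698 to 139.6 ± 11.5 CPM (2.29, SE 0.06), cyclin Ccna2 from 10.6 ± 0.228 to 51.4 ± 1.21 (2.28), Ccnb1 from 9.58 ± 0.202 to 44.1 ± 1.26 (2.2) and the spindle gene Tpx2 from 15.9 ± 0.552 to 69.6 ± 4.14 (2.13). Of 12 cell cycle exit genes, 7 were lower and 2 were higher (median -0.34, adjusted p 0.00871; adjusted p = 0.175 with an estimated correlation). The CDK inhibitor Cdkn1a (-1.23), the retinoblastoma gene Rb1 (-1.47) and cyclin Ccnd3 (-1.16) fell. Rb1 and Ccna2 share 14.9% and 12.5% of their exonic bases with neighbours. The mitochondrial share, the other-cell markers and the sex-linked transcripts differed between the same libraries, also for the lists that follow.

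Of 29 interferon response genes, 25 were lower and 2 were higher (median -1.09, adjusted p 8.41e-16; 0.0162 with an estimated correlation), with Ifi44 at -1.96, Gbp3 at -1.79, Ifit3 at -1.67 and Isg15 at -1.36. Of 19 chemokine and inflammation genes, 16 were lower and 3 were higher (median -1.03, adjusted p 1.1e-07; adjusted p = 0.0754 with an estimated correlation). Cxcl5, a neutrophil attractant, fell 15.4-fold, the prostaglandin synthase Ptgs2 8.54-fold from 510.5 ± 18.9 to 59.7 ± 4.97 CPM, Il6 8.37-fold and Csf1, the macrophage growth factor, 2.35-fold. Of 19 TGF-beta family targets, 14 were lower and 2 were higher (median -0.62, adjusted p 1.54e-06; 0.0386 with an estimated correlation). Among these the activin subunit Inhba (-2.21) and the activin antagonist Fst (-2.47) both fell, as did Ccn2 (-1.94; 23.2% of its exonic bases are shared).

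All 15 endothelial genes were lower (median -1.85, adjusted p 5.39e-11; 0.0386 with an estimated correlation), with Pecam1 at -3.18, from 49.6 ± 0.864 to 5.42 ± 0.87 CPM, Tie1 at -2.97, Vwf at -2.49 and Cdh5 at -1.82. Of 18 macrophage and leukocyte genes, 16 were higher and 2 were not called (median 1.77, adjusted p 2.28e-08; 0.0261 with an estimated correlation). Lysozyme Lyz2 rose from 82.5 ± 2.3 to 238.3 ± 2.96, Ctss by 2.44, Cd68 by 2.25 and Laptm5 by 1.67 on the log2 scale. Of 12 Schwann and neural genes, 10 were higher and 1 was lower (median 1.80, adjusted p 2.66e-10; 0.0278 with an estimated correlation), with the nerve growth factor receptor Ngfr going from 130 ± 2.47 to 518.9 ± 3.45 and the glial factor Sox10 from 31.7 ± 1.14 to 123.3 ± 4.58. Of 5 tenocyte genes, 4 were higher and 1 was lower (median 0.75, adjusted p 0.00324; adjusted p = 0.0754 with an estimated correlation). Thbs4 (4.31), Tnmd (3.07) and Mkx (0.75) rose, whereas the tendon transcription factor Scx fell by 1.6. The tenocyte call was lost with limma voom (adjusted p 0.137) and with no low-count filter (0.0539); over the alternatives its adjusted p ran from 0.00208 to 0.137. Of 15 smooth muscle and pericyte genes, 8 were lower and 3 were higher (median -0.30, adjusted p 0.00109; adjusted p = 0.157 with an estimated correlation), including the channel subunit Abcc9 (-2.70) and Rgs5 (-0.96). The fibro-adipogenic list (9 higher, 7 lower of 17; adjusted p 0.363), the adipocyte list (2 higher, 5 lower of 8; 0.0991) and the cartilage and bone list (3 higher, 4 lower of 8; 0.728) were not called, although the adipocyte list was called without WT replicate 2 (adjusted p 0.0441; 0.0441 to 0.147 over the alternatives). Spp1, the most abundant member of the last, fell 2.6-fold from 3347 ± 17.7 CPM, and 18.8% of its exonic bases are shared.

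Among matrix genes, 22 of 42 were higher and 15 lower (median 0.16, adjusted p 0.0206; adjusted p = 0.532 with an estimated correlation), and the call was lost without WT replicate 3 (adjusted p 0.0525), with limma voom (0.153), with no low-count filter (0.0845) and with GC and length offsets (0.0578). Over the alternatives its adjusted p ran from 0.00168 to 0.461. The collagen VI genes Col6a2 (1.99) and Col6a1 (1.71), the fibrillin Fbn2 (2.19) and elastin Eln (2.16) rose. Among the 15 that fell were Thbs1 (-1.12), from 2923 ± 102 to 1343 ± 64.8 CPM, and the collagen Col8a1 (-0.90), both named after their values were seen.

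All 13 tested genes of the mitochondrially encoded list, which does not hold every gene of that chromosome, were lower (median -1.38, adjusted p 5.73e-07; adjusted p = 0.0588 with an estimated correlation), with mt-Nd6 at -1.35, mt-Nd4 at -1.22 and mt-Co1 going from 19090 ± 378 to 9801 ± 656 CPM; these genes have nuclear copies that can share reads. Of 27 nuclear oxidative phosphorylation genes, 18 were lower and 0 higher (median -0.45, adjusted p 0.000599; adjusted p = 0.461 with an estimated correlation), among them Sdha (-0.86) and Ndufs1 (-0.80). Of 23 glycolysis and hypoxia genes, 19 were lower and 2 were higher (median -0.51, adjusted p 0.000667; adjusted p = 0.0899 with an estimated correlation). Egln3 (-1.55), Aldoa (-0.88) and Ldha (-0.82) fell and Ndrg1 rose (1.26). Of 32 ribosomal protein genes, 31 were higher (median 0.60, adjusted p 3.44e-07; adjusted p = 0.352 with an estimated correlation), with Rplp0 and Rpl3 both at 0.70. Of 18 cholesterol synthesis genes, 12 were higher and 4 lower (median 0.18, adjusted p 0.0134; adjusted p = 0.0899 with an estimated correlation), including Mvd (0.81) and Lss (0.78). Among 9 tested host genes of noncoding RNAs in muscle, 6 were higher and 3 lower (median 0.54, adjusted p 0.00487; adjusted p = 0.15 with an estimated correlation), with Meg3 at 1.35 and Gas5 at 1.2; limma voom gave an adjusted p of 0.0502, and the alternatives ran from 0.000154 to that value.

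Smarca5 fell and Ep300 rose, both by small amounts. Smarca5 (ENSMUSG00000031715, chromosome 8, 80698507 to 80739497) went from 118 ± 1.52 to 92.7 ± 10.1 CPM, a log2 fold change of -0.35 (SE 0.06, adjusted p 1.54e-05). Ep300, which encodes p300 (ENSMUSG00000055024, chromosome 15, 81585351 to 81652077), went from 87.8 ± 7.68 to 96.6 ± 2.09 (0.14, SE 0.05, adjusted p 0.0197). The Ep300 call was lost without WT replicate 1 (0.12, adjusted p 0.103), WT replicate 3 (0.07, 0.309) or KO replicate 1 (0.13, 0.0798), with DESeq2 (0.12, 0.117) and with GC and length offsets (0.04, 0.46), and over the alternatives other than the 1.5-fold test its adjusted p ran from 8.63e-07 to 0.46. Over 22 genes of the Smarca5 and p300 complexes, 10 were higher and 9 lower (median 0.04, mean -0.12), and camera did not call the list (direction lower, adjusted p 0.864). Its most abundant called members were Rbbp4 (-0.29; 18% of its exonic bases are shared) and Smarca4 (0.11, adjusted p 0.0277). The Smarca4 call was lost without WT replicate 1 (0.08, adjusted p 0.21), WT replicate 3 (0.07, 0.247) or KO replicate 1 (0.10, 0.0909), with median-of-ratios factors (0.0519), no low-count filter (0.0734), DESeq2 (0.128), GC and length offsets (0.0623) and the per-library tables (0.12, 0.0897). Outside the 1.5-fold test, which did not call it either, its adjusted p ran from 8.35e-07 to 0.247. The largest change in the list was that of Cecr2 (-2.14, SE 0.18), named after its value was seen, at 7.07 CPM in WT and 1.63 in KO.

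In all, camera called 25 of the 36 lists, 17 lower and 8 higher, and 14 of them with an estimated correlation, 11 lower and 3 higher. Of the lists not yet described, none was called: p53 targets (5 higher, 9 lower; adjusted p 0.153), immediate early genes (6 and 10; 0.678), unfolded protein and heat shock genes (6 and 10; 0.412), Notch (8 and 5; 0.704), Wnt (9 and 10; 0.405), IGF and growth signalling (6 and 11; 0.765) and replication-dependent histones (0 and 5; 0.363). Median and mean differed in sign for the heat shock list (-0.30 and 0.12, camera direction higher), the Notch list (0.29 and -0.37, direction lower) and the cartilage and bone list (-0.05 and 0.14, direction lower). In the growth list the binding protein Igfbp5 rose 2.15-fold, to 1609 ± 71.3 CPM, and the imprinted H19 RNA fell by 0.29 on the log2 scale from 10800 ± 160. In the Notch list the receptor Notch3 (0.34) and the ligand Jag1 (0.29) rose, whereas the ligands Dll4 (-3.54) and Jag2 (-2.66, from 90.1 ± 3.99 to 14.3 ± 0.28 CPM), named after their values were seen, fell. With library size only, the small falls of Hspa8 (-0.17) and Hist1h1c (-0.14) moved to 0 and 0.03. Adjusted over the list alone, the called counts of 34 lists were the same as over all genes tested, and Notch had 9 and ribosomal proteins 32 genes higher.

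The libraries also differed in sex-linked transcripts. Xist, the RNA of the inactive X chromosome, lay between 152.3 and 155.3 CPM in WT and between 416.8 and 478.4 in KO libraries (log2 fold change 1.57, SE 0.05, adjusted p 2.36e-24). Of 4 Y-linked genes, Ddx3y (-0.78, SE 0.06), Uty (-0.50, SE 0.09) and Eif2s3y (-0.42, SE 0.08) were lower in KO, and Kdm5d was not called (0.16, SE 0.08, adjusted p 0.101). These 5 genes were chosen after the data were seen.

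**Figure D3:**
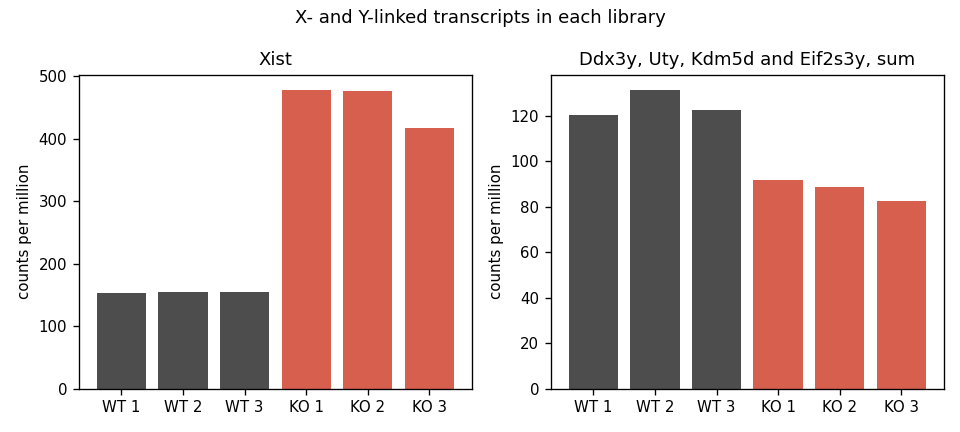
Xist (left) and the sum of 4 Y-linked genes (right) in each of the 6 libraries, in CPM on axes from 0; each bar is 1 library. Xist lies between 152.3 and 155.3 in WT and between 416.8 and 478.4 in KO libraries, and the Y-linked sum between 120.6 and 131.6 in WT and between 82.7 and 91.9 in KO libraries.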

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

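The per-library tables and their comparison with the matrix, the GC and length offsets and the thinning were chosen after the data were seen. Outside the 1.5-fold test and the per-library tables, the count of called genes stayed between 9641 (DESeq2) and 11055 (no low-count filter). Without 1 library it lay between 9766 and 10151. Of the 10353 main calls, 86.3% (library size only) to 98.9% (median of ratios) were kept with the same direction in these alternatives. Of the 138 genes chosen by the rule, 131 kept their direction and their side of the threshold in every one of them. Most of the 138 were chosen from these data for small p-values, large changes or high levels among called genes, which favours stable calls. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.001, -0.009 and -0.025, and with the number as a block 10209 genes were called, 5064 lower and 5145 higher, with 25 lists; among the rule's genes the block changed the call of Cd248 alone (adjusted p 0.0566), which 4 single libraries left out also ended (0.0608 to 0.15). Testing against a fold of 1.5 left 3394 genes, 1853 lower and 1541 higher, since small changes no longer count. With the matrix totals, the simulation of KO against WT recovered 92% of 2-fold changes, with far fewer genes changed than were called in the data. The repeat of camera with an estimated correlation left 14 called lists. Its adjusted p also rose for lists whose estimated correlation lay under the preset 0.01. For calcium handling (-0.026) camera's adjusted p went from 3.22e-49 to 0.0028, and for tenocyte genes (-0.113) from 0.00324 to 0.0754. For such lists a higher correlation is not the cause, and no other cause was tested. DESeq2 and the 1.5-fold test give no camera value. With library size only, Cd248 moved to 0.07, Hspa8 to 0 and Hist1h1c to 0.03, and with upper-quartile factors Cd248 to 0; these scalings shift the median of all genes to 0.192 and 0.122. The per-library tables gave 5436 calls among 9871 genes tested, 2745 lower and 2691 higher, and 2 called lists of 26 (sarcomere and mitochondrially encoded), and the cause was not tested. Of 4511 matrix calls tested there, 1906 (42.3%) were called in the same direction. In the stretches of chromosomes 4 and 6 where all counts compared match, 135 of 142 were and 0 changed sign. Matching counts of the same libraries can hardly give other calls, so this is no independent repeat. Over all genes with a matching mean count, in these stretches or not, 316 of 428 (73.8%) were and 70 (16.4%) changed sign; among genes with a mean of at least 200 and no match, 38.4% were and 38.9% changed sign. Outside those stretches and chromosomes M and Y, the counts argue against the values, as a set, belonging to the genes they are labelled with. For a single gene this is open, and a change of sign there need not be a failed repeat of that gene. Of the rule's genes measured in the per-library tables, 5 had a matching mean count and 50 did not. Of 55 rule genes measured there, 28 kept direction and call, 10 lost the call and 17, none with matching counts, had the opposite sign: Mymk (0.19), Itga7 (0.22), Megf10 (1.41), Ncam1 (0.77), Chrnb1 (0.91), Eno3 (0.32), Tpx2 (-0.28), Gsn (-0.32), Rgs5 (2.62), Laptm5 (-0.26), L1cam (-0.63), Spp1 (0.30), Il6 (0.02), Rbbp4 (0.47), Lss (-0.22), Aldoa (0.72) and Rpl32 (-2.11). In 9 lists camera's direction changed there, with called members in the matrix direction numbering 1 for satellite cell state, dystrophin complex and energy metabolism, 2 for cell cycle exit, smooth muscle, endothelial and glycolysis, 0 for chemokines and 3 for ribosomal proteins.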

Other observations

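The tests of cell types, sex-linked genes and noncoding genes were chosen after the values were seen, and so were the noncoding genes named. Among 958 tested genes that GENCODE M21 gives a long noncoding biotype, 300 were higher and 178 lower in KO. These biotypes include processed transcripts, among them genes such as Cct6a and Ifi30 that carry the names of protein-coding genes. Malat1, an abundant nuclear RNA, rose from 294.3 ± 7.54 to 935.1 ± 109 CPM (log2 fold change 1.67, SE 0.08; chromosome 19, 5795690 to 5802672), and the snoRNA host Snhg12 from 8.35 ± 0.193 to 24.5 ± 1.48 (1.55, SE 0.09; 19.6% of its exonic bases are shared with snoRNA genes). The largest falls among those with at least 5 CPM in the higher group were 2310043M15Rik, an antisense gene on chromosome 16 that shares 28% of its exonic bases with Dop1b (-3.13, SE 0.17), and Gm15564 (-2.65, SE 0.22). The largest rise was that of Gm12688 on chromosome 4, from 2.09 ± 0.398 to 12 ± 0.395 (2.50, SE 0.14).

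Of the 10 ways to split the 6 libraries into 3 and 3, 1 (the split by genotype) gave 10353 called genes, and the highest of the others gave 0. With 10 splits the share cannot fall under 10%, so they are too few for a share under 0.05.

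The lower muscle lists in KO were weighed against a lower share of muscle cells, GC content with gene length, and depth. A lower share of muscle cells alone, with the mix of the other cells unchanged, would raise the markers of every other cell type. The endothelial median was instead -1.85 (quartiles -2.56 and -1.17), while the macrophage median was 1.77 (quartiles 1.19 and 2.36). The fibro-adipogenic list, which was not called, had a median of 0.21. These values speak against that case only. A lower muscle share together with a changed mix of the other cells stays open. The median of the 52 sarcomere genes called lower was -1.87. It was -1.98 after offsets for GC content and exon length, which argues against GC content and length as the whole cause. After thinning to equal depth it was -1.86, but random thinning leaves the expected fold changes as they were, so this value cannot decide on depth. Library totals overlapped: WT replicate 2 had 20193337 counts, and KO replicates 1 and 2 had 20861627 and 23646805. Myh3 and Acta1, fixed by name beforehand, stood at 5968 and 5459 CPM in that WT library. In KO libraries they reached at most 1019 and 1555, which argues against depth as the whole cause for these genes. With the offsets and with thinning, 100% of the 52 sarcomere genes stayed called lower, a share that could hardly fall given their small p-values and that decides nothing by itself. A gain of the cell types whose markers rose stays open, and so does an effect of the genotype on the muscle cells; neither was tested.

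The non-muscle marker lists moved apart: 88.9% of macrophage genes and 83.3% of Schwann genes were called higher and 100% of endothelial genes lower, and 0 of their tested members are in another fixed list. The most abundant members were Lyz2 and Ngfr among those that rose, at 238.3 and 518.9 CPM in KO, and Cdh5, at 173.2 in WT, among those that fell. The other macrophage members were far lower in KO, from Ctss at 36.2 CPM down to Cd52 at 0.812, the last named after its value was seen. Neither a different cell make-up of the preparations nor an effect of the genotype on cells of these types was tested.

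Xist and the Y-linked genes were both present in all libraries, and their log2 ratio was 0.23 to 0.34 in WT and 2.33 to 2.43 in KO. This ratio spanned only 0.11 among WT and 0.09 among KO libraries. Whether the libraries of each genotype came from 1 pool of animals was not tested, and p-values would then measure technical spread only. In 6 of 6 libraries Xist and the Y-linked sum exceeded 1 CPM, which argues against each library coming from a single animal of one sex. A different mix of sexes as the whole cause would lower all 4 Y-linked genes alike, but the highest and the lowest, Kdm5d and Ddx3y, differed by 0.93 (SE 0.11) in log2 fold change. A different mix as part of the cause stays open, and so does an effect of the genotype or of cell type on these genes, which was not tested.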
